A study of Rattus norvegicus with 5 samples.

How the data were processed

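The series holds 5 samples of Fao rat hepatoma cells, 1 for each of 0, 15, 30, 45 and 60 min of 10 nM insulin. Per the labels' protocols, cells grew for 2 days in medium with 10% serum and were starved for 16 h with 10 nM dexamethasone before insulin, and 700 ng of total RNA was amplified and labelled with Cy3. Samples were grouped by the time in their labels. The labels give no replicate or culture numbers, so every group has 1 array.

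The deposited scanner files hold 45018 spots per array, 43379 of them not controls, on rat array design 014879, which is annotated on rn4. Per the file headers, intensity was read with Agilent Feature Extraction 9.5.3.1, which subtracted a spatially fitted background and corrected a multiplicative trend within each array, so the deposited intensity can be 0 or negative (14.34% to 17.21% of spots). The deposited flags for spots well above background, saturated spots and outliers were used as the software set them. No spot was saturated. The deposited series matrix holds log2 values of 19777 probes, 19746 of them not controls. The step that made it is not given in the sources used here. From the values, each column matched log2 of the processed signal over the 75th percentile of its array, centred on the median of each probe over the 5 arrays, with correlations of 0.9994 to 0.9999 across the probes well above background on all 5 arrays, which are not independent replicates. Its column medians were 0.00 on all 5 arrays and its standard deviations 0.166, 0.153, 0.131, 0.142 and 0.287 in order of time. Direction and scale were thus settled, while the rule that chose its probes stays unknown.

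From the scanner files, control spots and outlier spots (100 to 163 per array) were left out, the spots of a probe were averaged, and the processed signal was divided by the 75th percentile of its array. Values below the lowest signal well above background on that array were set to it, and log2 was taken. Of 41012 probes, 263 had 10 spots and the others 1. Probes were named through the accession in the files and a RefSeq gene table of assembly GRCr8, used for names only (10826 probes), or through a current or older symbol (8698 probes), and 21488 kept the name in the files. A gene was represented by its brightest probe. This gave 35632 genes or transcripts, 20510 of them well above background on at least 1 array (9994 with a gene symbol) and 16714 on all 5. Coordinates are those of the probes in the files, on rn4. No genome sequence was used here, so exons and untranslated regions were not assigned.

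A change is the difference in log2 between a time and 0 min. Where the gene was well above background on only 1 of the 2 arrays, the dimmer side was set to the higher of its own signal and the lowest signal well above background, and the change is a bound ("at least N-fold"). Where it was on neither, no change was given. A bound that uses the gene's own dim signal carries the noise of that signal. Genes at least 2-fold higher or lower were counted at each time. The trend over time was fitted with limma 3.58.1 (R 4.3.3) as a slope on time over 5 arrays with 3 residual degrees of freedom and 1 floor common to all arrays, with moderated variances and Benjamini-Hochberg adjustment at a 5% false discovery rate. For 19 gene lists fixed before the data were examined, the median change was set against 10000 random lists of the same size drawn from 20 bins of mean expression, and a median outside the 2.5 to 97.5 percentiles was called above or below. Of 337 list entries, 320 matched a gene on the array. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

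Genes were named by a rule also fixed before the data were examined. It took the 10 highest and 10 lowest by mean change at 30, 45 and 60 min among genes with a symbol and a 2-fold change in 1 direction at 2 or more times, the 3 largest increases and 3 largest decreases at each time measured on both arrays, up to 4 members of each list with the largest mean change, the 5 smallest trend p-values in each direction, and Egr1, Fos, Jun, Myc, Pck1, G6pc1, Igfbp1, Irs2, Srebf1, Insr, Actb and Gapdh whatever their change. This gave 115 genes, a few of which are not reported here.

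Signal over background sets the precision. Between 50.87% and 56.45% of non-control spots were well above background. Among probes with at least 8 usable spots, the median standard deviation between spots of an array was 0.121 to 0.139 log2 units, which gives a change a technical standard deviation of 0.171 to 0.197 within the arrays. Over genes on both arrays the standard deviation of the change was 0.227, 0.237, 0.251 and 0.343 at 15, 30, 45 and 60 min. The 8 labelled control transcripts detected, added to the samples, were 0.18, 0.15, 0.21 and 0.20 log2 units higher than at 0 min at these times on the scale used, and the median gene measured on both arrays was 0.02 to 0.03 higher.

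The counting rule, the list percentile and the trend fit were tested on simulated data. Over 16714 simulated genes with a noise of 0.2, the counting rule called 200 of 200 changed genes and 0 unchanged ones, and the list percentile called 100 of 100 lists of 15 genes shifted by 0.5 and 2 of 100 unshifted ones. The 0 holds for this noise only and does not carry over to the real counts, most of which are bounds. Resampled differences between the 30 and 45 min arrays gave on average 13.0 of 16714 unchanged genes 2-fold higher. Over 20510 simulated genes the limma trend called 33 of 100 genes changed by 1 log2 unit over the hour, 94 of 100 changed by 2, and 11 unchanged genes. These changes lay on an exact line with normal noise, so the shares do not carry over to the real data.

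Alternatives were quantile scaling, scaling on the median of detected probes, normexp background with an offset of 50, the series matrix values, the mean over detected probes, a filter on genes well above background on all 5 arrays, no filter on dim probes, outlier spots kept, and the mean of the other arrays as the reference. For the trend they also included each array left out, slide as a covariate, an intensity trend in the prior variance and a quadratic term. Slide as a covariate fits the 60 min array by itself. The 15 min array as the reference, the lasting changes on slide 1 alone, and normexp without 6 spots of extreme local background were added after the data were seen. The planned normexp fit was distorted on the 15 min array, where these 6 spots, with a local background of up to 6041 against a median of 43, moved the fitted background mean to −215.9, and to −8.9 without them.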

Results

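Fao cells, a differentiated rat hepatoma line that keeps many functions of hepatocytes, were starved for 16 h with 10 nM dexamethasone, a synthetic glucocorticoid, and then given 10 nM insulin. Total RNA from 0, 15, 30, 45 and 60 min of insulin was measured on 5 Agilent 1-colour rat expression arrays, with 1 array per time. No time had a replicate, so a value at a single time against 0 min carries no p-value, and the number of arrays limits the precision. Of 43379 non-control spots per array, 22069 to 22819 were well above background on the arrays of 0 to 45 min and 24489 on the 60 min array. The arrays of 0, 15, 30 and 45 min lay on slide 1 and were scanned together, whereas the 60 min array lay on slide 2 and had its own scan. Slide and time therefore cannot be told apart at 60 min. Within slide 1 the positions of the arrays followed the order of time, so position and time cannot be told apart there. The 75th percentile of signal was 480.3 on the 60 min array and 253.6 to 299.9 on the others. Cells kept for the same times without insulin were not analysed here, so each value below compares a time after insulin with the single 0 min array.

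The first comparison asked which transcripts differed from 0 min at each time after insulin. Immediate early genes, which code mostly for transcription factors that cells induce first after a stimulus, gave the largest increases at 30 min among genes with a symbol measured on both arrays. Egr2 was 5.49-fold higher at 30 min than at 0 min, Jun 3.97-fold, Atf3, a stress-responsive transcription factor, 3.70-fold, and Fos, the partner of Jun in the AP-1 complex, 3.27-fold. Egr1 was 1.96-fold higher at 30 min. At 60 min Fos was 5.11-fold lower than at 0 min, Egr1 3.98-fold lower and Egr2 2.37-fold lower. Nr4a3, an orphan nuclear receptor, followed another course and was 2.33-fold higher at 30 min, 5.03-fold higher at 45 min and 4.67-fold higher at 60 min.

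Over the fixed list of immediate early genes, 29 of 30 measured members were above their 0 min level at 30 min, 11 of them by at least 2-fold, and none was 2-fold lower. The median log2 change was 0.66 at 30 min, where 95% of 10000 random lists matched on expression gave medians between −0.05 and 0.10. At 45 min the median was 0.37, also above the random lists, with 4 members 2-fold higher and 1 lower. At 15 min the median was −0.06 and lay just below the random range of −0.04 to 0.10, and at 60 min it was 0.02 and lay inside it, with 2 members 2-fold higher and 4 lower. Myc, a growth-promoting transcription factor of the same list, had log2 changes between −0.36 and 0.20. The probes named here lie, on the rn4 assembly used by the array design, at chromosome 20, 21883940 to 21883999 for Egr2, chromosome 5, 115358764 to 115358823 for Jun, chromosome 6, 109561099 to 109561158 for Fos, and chromosome 18, 27347173 to 27347232 for Egr1.

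Genes that limit ERK signalling had smaller median changes than the immediate early genes at 30 and 45 min, but not at 15 min. Dusp1, a phosphatase of MAP kinases, was 1.79-fold higher at 15 min and 1.90-fold lower at 60 min, Dusp5, a nuclear phosphatase of ERK, was 2.16-fold higher at 30 min, and Phlda1 was 2.36-fold higher at 60 min. The list of ERK feedback genes had a median log2 change of −0.17 at 15 min, below random lists, and of 0.20 at 30 min, above them. Its medians of 0.04 at 45 min and −0.02 at 60 min lay inside the random range. Of 11 or 12 measured members, 1 was 2-fold higher at 30 min and 1 at 60 min, and none was 2-fold lower. With normexp background refitted without 6 distorting spots, a setting chosen after the data were seen, the medians at 15 and 30 min were −0.04 and 0.11, inside the random range. Planned settings also removed these calls. Both were lost with normexp on all spots and with no filter on dim probes. The 15 min call was also lost with the series matrix values and among genes well above background on all 5 arrays, and was kept in 4 of 9 alternatives.

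**Figure D1:**
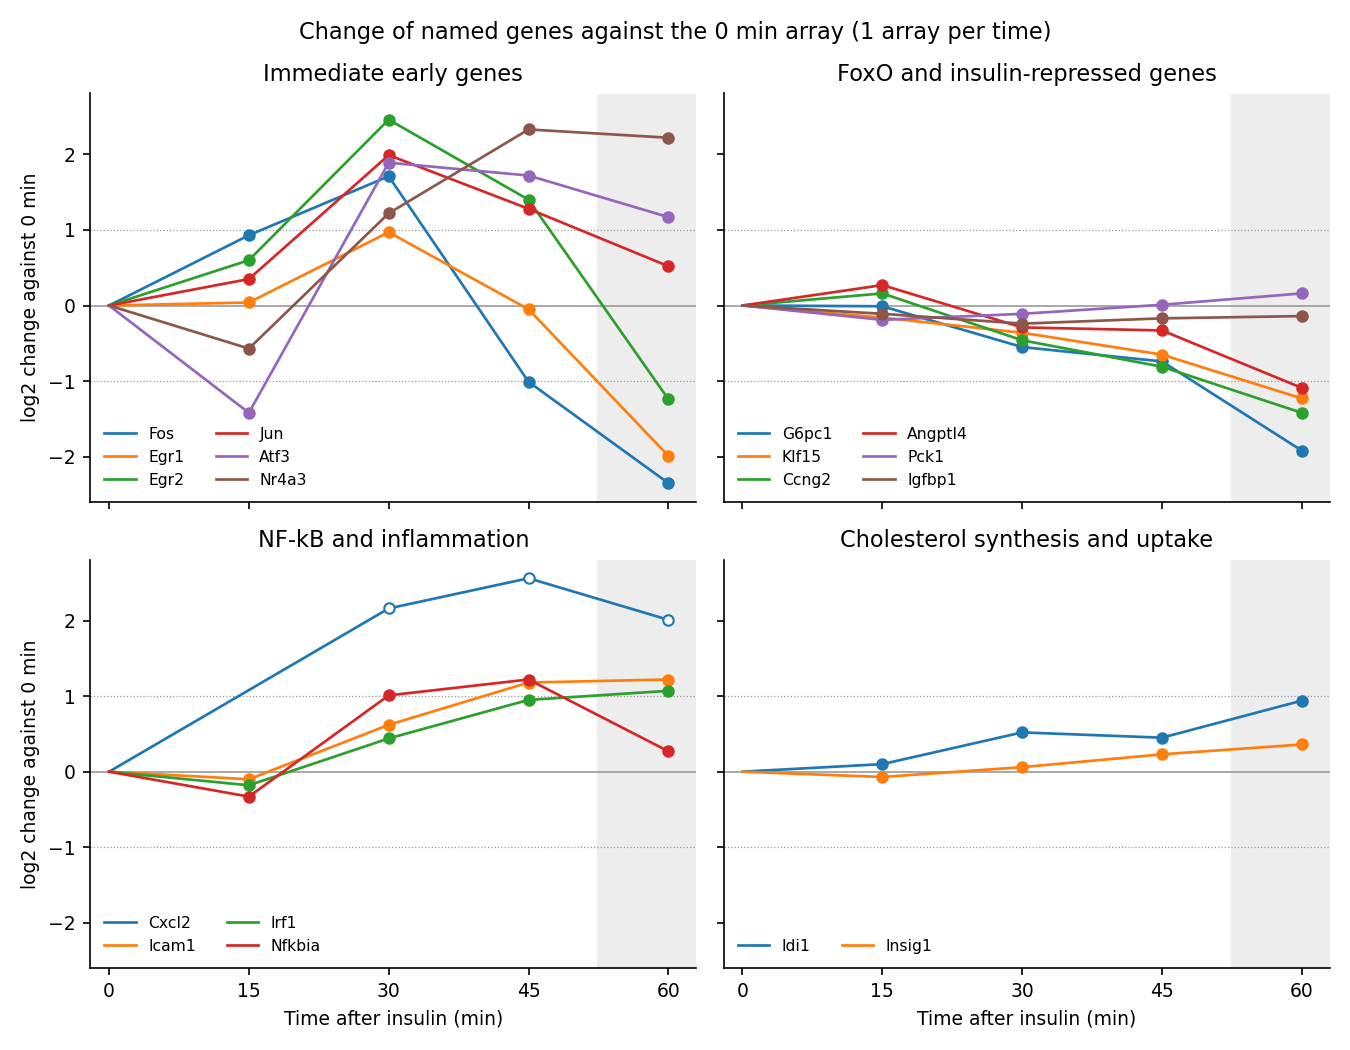
Log2 change against the 0 min array (vertical axis) by time after insulin in min (horizontal axis) for named genes of 4 fixed lists, with 1 array per time and no error bars. Filled points were well above background on both arrays, open points are lower bounds, dotted lines mark 2-fold, and grey marks the 60 min array on slide 2. Egr2, Jun, Atf3 and Fos stand highest in their panel at 30 min, and G6pc1 is at −1.92 at 60 min.

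Genes that insulin is known to repress through FoxO transcription factors were lower as a group from 30 min on. G6pc1, the catalytic subunit of glucose-6-phosphatase and the last step of glucose output, was 1.46-fold lower at 30 min, 1.67-fold lower at 45 min and 3.79-fold lower at 60 min. A second G6pc1 probe gave log2 changes of −0.27, −0.82 and −2.21 at these times. Ccng2, an atypical cyclin under FoxO control, was 2.67-fold lower at 60 min, Klf15, a transcription factor that activates gluconeogenic genes, was 2.34-fold lower, and Angptl4, a secreted inhibitor of lipoprotein lipase, was 2.14-fold lower. The list median was −0.02 at 15 min, inside the random range, and −0.21, −0.10 and −0.37 at 30, 45 and 60 min, each below it. At 60 min 14 of the 18 measured members were at or below their 0 min level, 4 of them by at least 2-fold.

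Other classical insulin targets moved little within the hour. Pck1, the rate-limiting enzyme of gluconeogenesis, had log2 changes between −0.19 and 0.16, Igfbp1, a secreted binder of insulin-like growth factors, between −0.24 and −0.11, and Irs2, an adaptor of the insulin receptor, between −0.36 and −0.03, with values down to −0.69 by its other probes. The receptor gene Insr was between −0.08 and 0.59. The gluconeogenesis list had medians of −0.13 at 15 min and −0.08 at 30 min, both below random lists, and of −0.02 and 0.10 at 45 and 60 min, inside them. G6pc1 was the only 1 of its 11 measured members 2-fold lower at any time. Against the 15 min array, a reference chosen after the data were seen, its 30 min median was 0.03. The probe of G6pc1 lies at chromosome 10, 90403940 to 90403999, and that of Pck1 at chromosome 3, 164017597 to 164017656 (rn4).

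Genes of the NF-kB and inflammation list were higher from 30 min on. Cxcl2, a neutrophil-attracting chemokine, was not well above background at 0 or 15 min and was at least 4.45-fold higher at 30 min, at least 5.91-fold at 45 min and at least 4.04-fold at 60 min. These bounds use its own dim 0 min signal and carry the noise of that signal. Icam1, an adhesion molecule, was 2.26-fold higher at 45 min and 2.33-fold at 60 min, and the transcription factor Irf1 1.93-fold and 2.10-fold. Nfkbia, the inhibitor that holds NF-kB in the cytoplasm, was 2.02-fold higher at 30 min, 2.32-fold at 45 min and 1.21-fold at 60 min by its brightest probe, but a second probe gave log2 changes of 1.04, 0.18 and −1.20, so its course after 30 min is unsettled. The list median was −0.19 at 15 min, below random lists, and 0.41, 0.61 and 0.35 at the later times, all above them. Of 12 measured members, 3 were 2-fold higher at 30 min and 4 at 45 and at 60 min. Another member, the chemokine Cxcl1, was 2.74-fold lower at 15 min and 2.13-fold lower at 60 min. Outside the list, the chemokine Cxcl10 was 3.89-fold higher at 60 min.

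Sterol genes stood apart at 60 min and fatty acid genes at no time. Idi1, the isopentenyl diphosphate isomerase, was 1.92-fold higher at 60 min by its brightest probe, with a log2 change of only 0.24 by a second one. Insig1, which retains the sterol sensor in the endoplasmic reticulum, was 1.29-fold higher. The list of cholesterol synthesis and uptake had a median log2 change of 0.23 at 60 min, above random lists, with 13 of 17 members above 0 and none 2-fold lower, and of −0.03, 0.04 and 0.04 before that, inside them. With normexp background the 60 min median was 0.19 and lay inside the random range. The fatty acid synthesis list, with 13 measured members and none 2-fold different, lay inside the random range at all 4 times, at 0.11, 0.05, −0.02 and 0.01, and Srebf1, its main transcription factor, was between −0.07 and 0.22, with −0.39 at 60 min by a second probe. The list of glycolysis and glucose entry, with 18 measured members, was above random lists at 30 min, at 0.15, and inside them at 0.08, 0.08 and −0.05 at 15, 45 and 60 min. With the mean over detected probes the 30 min median was 0.05, inside the random range. Pfkfb3, which makes the activator of phosphofructokinase, was 1.83-fold higher at 15 min and, as the only 2-fold member, 2.04-fold lower at 60 min.

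Clock and glucocorticoid-induced genes included members that were higher late in the hour. Per2, a repressor of the circadian clock, was 2.65-fold higher at 60 min, Per1, a second one, 1.68-fold, and Per3 was 1.27-fold lower. Bhlhe40, another clock repressor, had a log2 change of 1.32 at 60 min. The clock list, with 10 to 13 measured members, had medians of 0.00 at 15 min, 0.11 at 30 min and −0.06 at 60 min, inside the random range, and of 0.27 at 45 min, above it. Glucocorticoid-induced genes, with 15 or 16 measured members, had medians of −0.13 at 15 min, below random lists, of 0.16 and 0.21 at 30 and 45 min, above them, and of 0.16 at 60 min, inside the wider range of that array. Dexamethasone had been present since the starvation began. Its members moved both ways at 60 min, with 10 of 16 above 0, 1 of them 2-fold higher and 1 member 2-fold lower. Per1 and Cebpb, a transcription factor of liver genes, had log2 changes of 0.75 and 0.66, and Angptl4, Dusp1 and Tsc22d3 of −1.09, −0.93 and −0.48. The 2-fold higher member, Mt1, was at −0.02 by a second probe.

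Lists of stress, growth and cell cycle genes went in different directions. The ATF4 and amino acid response list, which marks a shortage of amino acids, had a median of −0.20 at 15 min with none of 16 members above 0, and of −0.16 at 30 min. Both lay below random lists, while 0.11 at 45 min and −0.10 at 60 min lay inside them. Sesn2, a leucine sensor, was 1.72-fold lower at 15 min. The 15 measured cell cycle genes had medians of 0.13 and 0.15 at 15 and 30 min, above random lists, and of −0.11 and −0.29 at 45 and 60 min, below them, with none 2-fold different. With the same refitted normexp background the first 2 were 0.09 and 0.09, inside the random range. With the mean over detected probes the 60 min median was −0.127, also inside it. The 15 min call was also lost with quantile scaling and with normexp on all spots. The 30 min call was kept in 5 of 10 alternatives. It was also lost with normexp on all spots, the mean over detected probes, no filter on dim probes and the 15 min array as reference. The 45 min call was lost with no filter on dim probes. The replication helicase genes Mcm2 and Mcm5 were 1.39-fold and 1.41-fold lower at 60 min, and Rrm2, a subunit of ribonucleotide reductase, was 1.47-fold higher. Second probes of Mcm2 and Rrm2 gave log2 changes of −0.11 and 0.13. The 15 measured hypoxia targets were above random lists at 15 min, at 0.18, and inside them at 0.09, −0.01 and −0.04 later, and Ankrd37, a target of HIF-1, was 2.44-fold lower at 60 min. The ribosome biogenesis list, with 16 measured members, lay inside the random range at −0.05, 0.03, 0.11 and 0.13, and Rrs1, a ribosome assembly factor, was 1.54-fold higher at 60 min. The unfolded protein response list, with 11, did so at 0.04, 0.13, 0.09 and −0.01, and the heat shock list, with 10, at 0.02, −0.03, −0.02 and 0.06. Dnajb1, a co-chaperone of Hsp70, was 1.60-fold higher at 60 min, with a log2 change of 0.23 by a second probe.

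The 17 or 18 measured genes of hepatocyte identity had medians of 0.06, 0.08, 0.17 and 0.06, of which the value at 45 min lay above random lists, and Fgg, the fibrinogen gamma chain, was 1.65-fold higher at 60 min by its brightest probe, with a log2 change of 0.09 by a second one. The 9 measured markers of macrophages, endothelium, stellate and biliary cells lay inside the random range at all 4 times, with medians of 0.00, 0.01, 0.02 and −0.14. The 14 measured housekeeping genes did so too, at −0.01, −0.01, −0.05 and 0.03. Within that list Actb, cytoplasmic beta actin, was 1.47-fold higher at 30 min with a log2 change of 0.49 at 45 min, and Gapdh, of the glycolysis list, was 1.24-fold higher at 60 min, with a log2 change of −0.08 by a second probe. Over the 19 lists and 4 times, 15 medians lay above the random lists, 13 below and 48 inside. Of these 28 calls, 12 were kept under every alternative setting: those of the NF-kB list and the FoxO list at 30, 45 and 60 min, of the immediate early genes at 30 and 45 min, of the clock and glucocorticoid-induced lists at 45 min, and of the ATF4 and gluconeogenesis lists at 15 min. The other 16 were lost under at least 1 setting. The calls kept at 15 min could not be tested with the 15 min array as reference. Under that reference the ATF4, gluconeogenesis, glycolysis, glucocorticoid-induced and cell cycle lists lost their calls at 30 min. The hepatocyte identity list lost its call at 45 min. The random lists assume that genes vary independently, so these percentiles describe the 5 arrays and are not p-values.

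**Figure D2:**
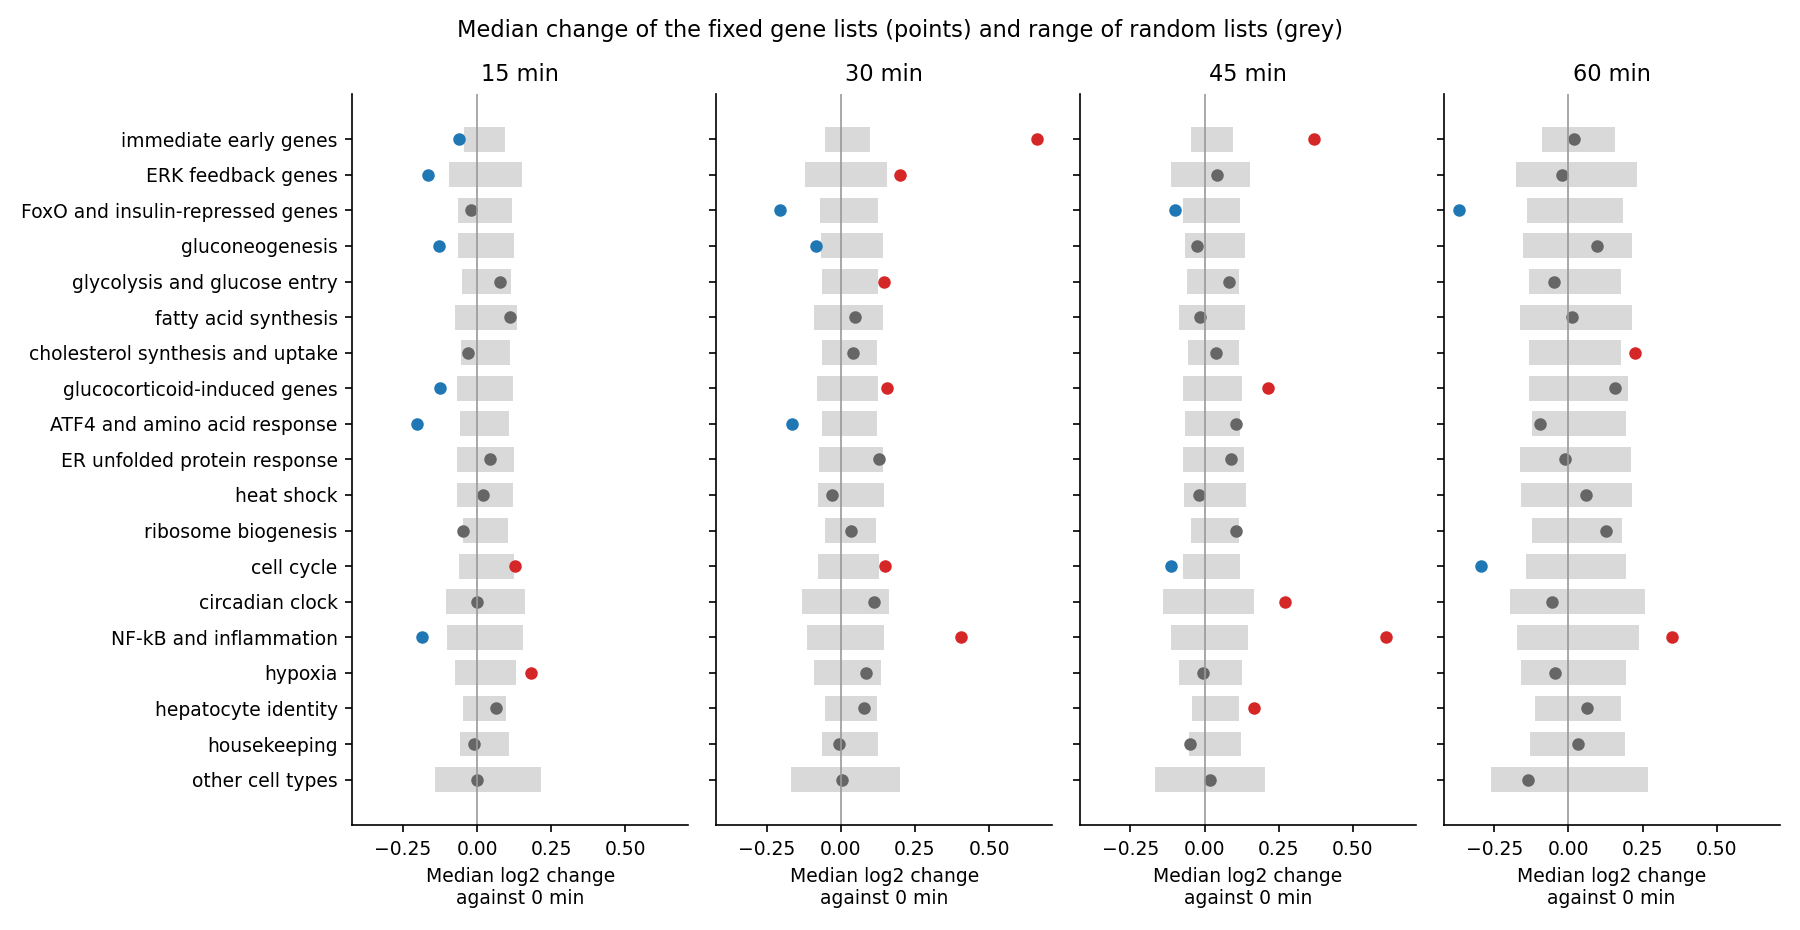
Median log2 change against the 0 min array (horizontal axis) for the 19 fixed gene lists (vertical axis) at 15, 30, 45 and 60 min. Points are list medians, red above, blue below and dark grey inside the grey bars, which span 95% of 10000 random lists matched on expression. The immediate early genes reach 0.66 at 30 min and the FoxO and insulin-repressed genes −0.37 at 60 min.

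Counted over all measured genes and transcripts, the 2-fold threshold was passed most often at 60 min. At 15 min 180 of 18546 were at least 2-fold higher and 264 lower, at 30 min 192 and 214 of 18434, at 45 min 247 and 287 of 18574, and at 60 min 400 and 360 of 19598. Most of these were bounds, because the gene was well above background on only 1 of the 2 arrays. On both arrays, 19 were higher and 48 lower at 15 min, 40 and 36 at 30 min, 56 and 47 at 45 min, and 117 and 122 at 60 min. Notch2, a receptor of cell contact signals, at 3.56-fold, Xpr1, a phosphate exporter, at 3.04-fold and Clec4f at 2.45-fold were the largest increases at 15 min among genes with a symbol measured on both arrays. Trib1, a pseudokinase, at 3.14-fold, Tmem245 at a log2 change of −1.59 and Cxcl1 were the largest decreases there. Notch2, Xpr1 and Clec4f were dim at 0 min, with log2 levels of −3.62, −3.72 and −3.92. At 30 min their log2 changes were 0.38, 0.15 and −0.06. Among genes with a symbol measured on both arrays, at 30 min the largest decreases were those of Rsph3 at 2.82-fold, Gdf6 at 2.22-fold and Sufu at 2.17-fold, and at 45 min Npas3 at 4.13-fold, Rad54b at 3.30-fold and Rsph3 at 2.48-fold. Sufu was already at a log2 change of −1.11 at 15 min and was at −1.0 at 60 min. All its changes rest on the same single 0 min value. Prickle1, a planar polarity gene, was 4.28-fold higher at 60 min by its brightest probe, but the mean over its detected probes gave a log2 change of −0.18.

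In place of replicates, the difference between the 30 and 45 min arrays served as the noise of an unchanged pair. Among 16714 genes well above background on all 5 arrays, 100 simulations without change gave on average 13.0 genes 2-fold higher, with at most 25, and at most 24 lower. Real change between 30 and 45 min is part of this noise. However, this pair had the fewest genes 2-fold apart on both arrays of all pairs, at 46. It also holds no difference between slides. The noise may therefore be too low for other pairs, and an excess over it is no proof of change. The observed counts were 12, 31, 43 and 98 higher and 36, 33, 44 and 86 lower at 15, 30, 45 and 60 min, so the count of higher genes at 15 min did not exceed this noise. Pairs of arrays on slide 1 had 46 to 104 genes 2-fold apart on both arrays, and pairs with the 60 min array 120 to 256.

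**Figure D3:**
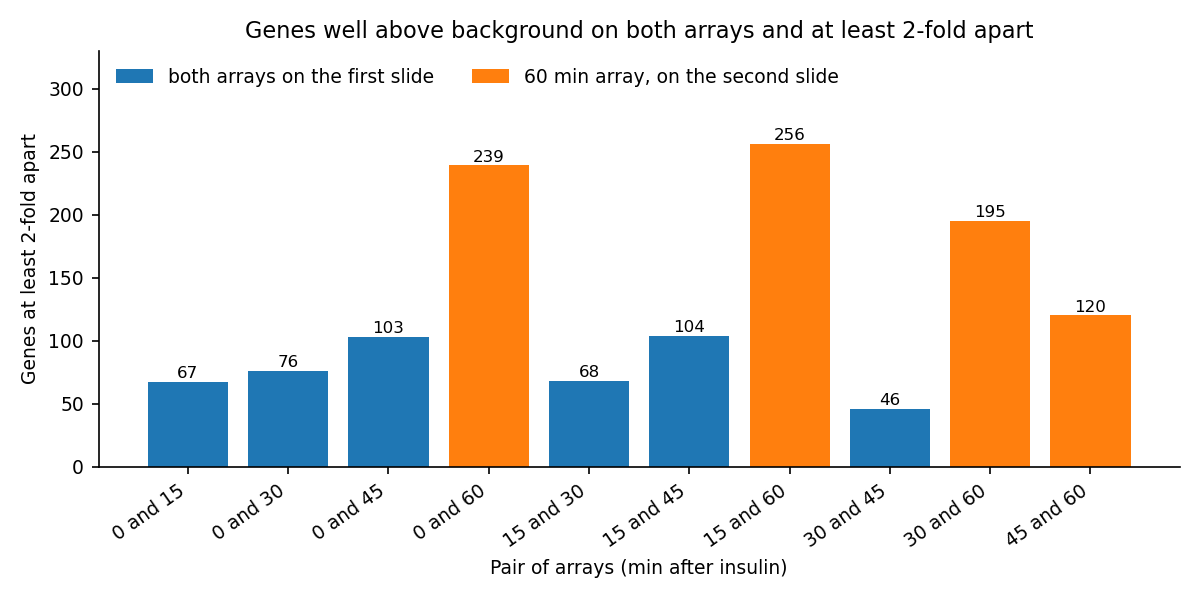
Number of genes at least 2-fold apart and well above background on both arrays (vertical axis) for each pair of arrays, named by their times in min (horizontal axis). Blue bars are pairs within slide 1, with 46 to 104 genes, and orange bars are pairs with the 60 min array on slide 2, with 120 to 256 genes.

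The next comparison asked which changes lasted, meaning a 2-fold difference from 0 min in 1 direction at 2 or more times. Slc30a1, the zinc exporter of the plasma membrane, was 5.13-fold higher at 45 min and 7.28-fold at 60 min, and the folds below are given in the same order. By mean change over 30, 45 and 60 min it came after the bound for Cxcl2. The higher genes also included Nr4a3, Atf3 and Cxcl10 and the small GTPase genes Rnd1, at 4.18-fold and 4.12-fold, and Rhob, at 2.60-fold and 2.18-fold. Ddah2, which degrades methylarginines that inhibit nitric oxide synthase, was 2.87-fold and 3.85-fold higher. Ankrd23, a muscle ankyrin repeat gene, was a bound only, at least 3.34-fold higher at 45 min. The probe of Slc30a1 lies at chromosome 13, 107983689 to 107983748, and that of Nr4a3 at chromosome 5, 64753210 to 64753269 (rn4).

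In all, 95 genes or transcripts were lastingly higher and 278 lower, of which 37 and 89 had a gene symbol. The 10 lower genes named by the rule (Or2h1b, Spon1, Ntn4, Ccdc54, Allc, Vsig4, Myt1, Snx20, Or52e2 and Npas3) were well above background at 0 min and, apart from Npas3 at 45 and 60 min, not at later times. The odorant receptor gene Or2h1b, for example, was at least 11.3-fold lower at 30 min. With any other array as the reference, 197 to 346 genes were lastingly lower than it and 57 to 126 higher, so a set of this size was not particular to the 0 min array. All comparisons share the 0 min array, and simulated unchanged arrays gave on average 8.0 lasting higher and 5.1 lasting lower genes, against 39 and 44 observed among the 16714 genes. The simulated arrays share their reference too, but their noise is that of the 30 and 45 min arrays, the closest pair, without a slide difference. On slide 1 alone, a choice made after the data were seen, 39 genes were lastingly higher and 250 lower.

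The last comparison asked whether expression followed a line over the 5 times. Among genes with a symbol, those ranked first for an increase by limma were Ddah2 and Kbtbd8, each with an adjusted p of 0.368, Sertad1, a cell cycle regulator, Prkab2, a subunit of AMP-activated kinase, and Tnfrsf12a, the receptor of TWEAK. Those ranked first for a decrease were Rad54b, a DNA repair helicase, Klf15, Ripor2, Ptprk and Ccng2, each with an adjusted p of 0.488. None of 20510 genes or transcripts passed a 5% false discovery rate, so 0 were called rising and 0 falling by limma, while 1104 had a positive and 689 a negative slope at an unadjusted p under 0.05. Among genes well above background on all 5 arrays, 3 were called rising and 1 falling, and with the series matrix values 1 and 1. Without the 60 min array 0 were called in either direction, with 790 and 679 at an unadjusted p under 0.05. In simulated data with the same spread, the fit called 33 of 100 genes with a log2 change of 1 over the hour. It called 94 of 100 with a change of 2, and 11 unchanged genes. The simulated changes lay on an exact line with normal noise, and the adjusted cutoff depends on how many genes change. These shares therefore do not carry over to the real data, where Ddah2, with a log2 change of 1.95 at 60 min, was not called.

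No member of any of the 19 fixed lists passed the trend test over all genes. Each list was then adjusted by itself, with no adjustment across the lists. The p-values measure scatter about a straight line over 5 single arrays, not the spread between replicates. Adjusted over the list alone, 5 NF-kB genes (Rel, Cxcl2, Icam1, Birc3 and Irf1), 4 clock genes (Per1, Per2, Bhlhe40 and Rora), 3 FoxO and insulin-repressed genes (G6pc1, Klf15 and Ccng2) and 3 glucocorticoid-induced genes (Tsc22d3, Per1 and Cebpb) passed. So did Idi1 among 17 cholesterol genes, Phlda1 among 12 ERK feedback genes, G6pc1 among 11 gluconeogenesis genes and Ankrd37 among 15 hypoxia targets. In the other 11 lists, immediate early genes among them with 31 tested, 0 passed by limma adjusted over the list alone. A rise and fall within the hour, as for Fos and Egr2, counts as scatter in this fit. The 0 is therefore no evidence against the changes at 30 min. Rel, Birc3, Rora and Tsc22d3 were named after their values were seen, and a second Tsc22d3 probe had a log2 change of −0.03 at 60 min. Of these genes, G6pc1, Klf15, Ccng2, Tsc22d3 and Ankrd37 had negative slopes and the others positive ones. Neither Cxcl2 nor Rora was well above background both at 0 min and at a later time, so their slopes rest partly on dim values.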

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

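The 15 min array as the reference, slide 1 alone for lasting changes, the other settings for lasting changes, and normexp without 6 spots of extreme local background were chosen after the data were seen. Among alternative values of list medians, 690 kept their direction and their side of the random range, 30 lost their call, 16 gained one and 5 reversed. Among those of named genes 946 kept theirs, 34 lost a 2-fold change, 3 gained one and 2 reversed. No change of scaling moved a 2-fold count by over 1.5 times. Signal over background sets most counts, because genes seen on 1 array only enter as bounds.

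With genes well above background on all 5 arrays, the higher and lower counts were 12 and 36 at 15 min, 31 and 33 at 30 min, 43 and 44 at 45 min and 98 and 86 at 60 min, and 39 and 44 lasting. The series matrix values gave 12 and 36, 31 and 33, 43 and 42, 91 and 89, and 38 and 44 lasting. Both settings test fewer genes. With no filter on dim probes the counts were 2302 and 2101, 2501 and 2131, 2054 and 2431, 1794 and 3503, and 2115 and 2587 lasting. Normexp, whose offset of 50 shrinks dim changes, gave 3290 and 50 at 15 min, 14 and 21 at 30 min, 27 and 22 at 45 min, 49 and 89 at 60 min, and 24 and 23 lasting. Without the 6 spots it gave 5 and 26 at 15 min, 14 and 21, 27 and 22, 49 and 91, and 22 and 22 lasting, so those spots made the 3290. Against the mean of the other 4 arrays, 60, 21 and 26 genes were lower at 15, 30 and 45 min. On slide 1 alone 39 genes were lastingly higher. For all other changes in these counts the cause was not tested.

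The trend gave 0 rising and 0 falling genes in every fit with an array left out (range 0 to 0 for both), with slide, with an intensity trend and with the quadratic term. It gave 3 rising and 1 falling among genes on all 5 arrays, and 1 and 1 with the series matrix values, and the cause was not tested.

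At 60 min the cholesterol list was at 0.186 with normexp, with or without the 6 spots, inside the random range. The cell cycle list was at −0.127 with the mean over detected probes, also inside it, and the ATF4 list at 0.209 against the 15 min array, above it. At 15 min, normexp on all spots turned the cell cycle list to −0.304 and the hypoxia list to −0.249, and put the immediate early genes, at −0.198, above its random lists. These 3 reversals were absent without the 6 spots. Against the 15 min array, the gluconeogenesis list at 30 min was at 0.03 and the ATF4 list at 0.062. Prickle1 at 60 min was at −0.18 with the mean over detected probes, and Trib1 at 15 min at 0.25 with normexp on all spots. Without the 6 spots the value of Trib1 was negative. For the other values of this paragraph the cause was not tested.

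No paired analysis was possible because each time has 1 array and the labels give no replicate numbers.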

Other observations

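The tests on metallothionein-2 and on the order of the arrays, the glucocorticoid-induced list at 45 min, the probe agreement of changes from 0 min and the use of the 15 min array as reference were chosen after the results were seen. The other tests were set after the counts and list medians had been seen and before their own values were computed.

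Slc30a1, which exports zinc from the cell, had the largest increase at 45 and at 60 min among genes with a symbol measured on both arrays, with log2 changes of −0.32, 0.96, 2.36 and 2.86 at 15, 30, 45 and 60 min. Mt1, a metallothionein that binds zinc and copper, was 2.92-fold higher at 45 min and 2.64-fold at 60 min by its brightest probe, after −0.84 and 0.64. A second probe gave −0.71, 0.54, 0.93 and −0.02, so the probes disagree at 60 min. Both genes were below their 0 min level at 15 min, as were Atf3 at −1.42, Nr4a3 at −0.57 and Rnd1 at −0.44, all of which were higher from 30 min on.

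Of the 5 genes named because they ranked first for an increasing trend, 4 were well above background on all 5 arrays. These had a higher value at each step from 15 to 60 min. The ranking itself favours such a course, so it is no separate support for a trend. Ddah2 had log2 changes of 0.42, 0.77, 1.52 and 1.95, Kbtbd8, an adaptor of a ubiquitin ligase, 0.27, 0.83, 1.08 and 1.47, Sertad1 0.42, 0.80, 1.03 and 1.22, and Tnfrsf12a 0.05, 0.60, 0.94 and 1.08. Their values at 15, 30 and 45 min come from slide 1 alone.

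The median change of the immediate early genes at 30 min did not come from the 0 min array and was not removed by quantile scaling. Its lowest value under quantile scaling, median scaling, normexp background and the series matrix values was 0.54, above random lists in each. Against the 15 min array the list median was 0.78. The other detected probes of these genes, 10 probes of 9 genes, had a median of 0.53. Those of Jund and Ifrd1 were lower than at 0 min and the rest higher. Egr2, Jun, Atf3, Fos and Egr1 had no other detected probe. Single probes are therefore excluded as a source only for the 9 genes as a group. The 0, 15 and 30 min arrays share slide 1, so a difference between slides is no explanation. Their positions on the slide followed the order of time, so an effect of position cannot be told apart from time. A response to insulin may therefore underlie the 0.54 or more, as a hypothesis, but a response to handling or to fresh medium stays open, since no array of cells treated without insulin was analysed here.

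The larger number of genes 2-fold apart at 60 min did not come only from dim genes that the brighter array detected. Among 10253 genes above the median level on all 5 arrays, the counts were 37 at 45 min and 63 at 60 min, a ratio of 1.70. With quantile scaling the ratio over all genes was 1.43 (537 and 767), which lies between the bounds set for and against an intensity-dependent difference of the second slide and leaves it open. The change from 45 to 60 min correlated across 2511 genes at 0.104 between 2 probes of a gene, against 0.385 from 30 to 45 min, a difference of −0.28. This met the condition set for probe-level noise of the second slide. Changes from 15 min correlated at 0.339 to 60 min and 0.576 to 45 min, and those from 30 min at 0.184 and 0.385. Changes from 0 min, on which the counts rest, show no such loss, at 0.319 for 60 min and 0.299 to 0.384 for the other times. The references thus differ, so whether probe-level noise of the second slide adds to the excess stays open. Slide 2 holds the 60 min array alone, so a later response to insulin and a slide effect cannot be told apart.

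For Slc30a1 and Mt1, a response to a metal is a candidate explanation, because metallothionein-2, named by its description in the files, was also higher, with log2 changes of −0.43, 0.48, 1.56 and 2.18. Its values had been displayed, under a transcript identifier, before the test was chosen. A glucocorticoid response, which also induces metallothioneins, stays open: the glucocorticoid-induced list without metallothioneins had a median of 0.13 at 60 min, at the 85.6 percentile of random lists, but of 0.17 at 45 min, at the 99.7 percentile. The bound set for this test named 60 min alone, and the 45 min value was added once the 60 min value was known, because the pattern includes 45 min. Zinc was not measured, and the second Mt1 probe at −0.02 weakens the pattern at 60 min.

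The order of the arrays was also tested. Of the 60 orders of the 5 arrays, 9 gave at least as many genes with an unadjusted limma p under 0.05 as the 1793 of the real order, which is 1 of them, so chance cannot be excluded for that number. The highest other order gave 2899. In all 9 the 60 min array, the one on slide 2, stood at an end, but other orders with it at an end gave as few as 673, and orders with it elsewhere gave up to 958, so its position alone does not set the number.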
